A study of Mus musculus with 6 samples.

How the data were processed

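Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse brown pre-adipocytes, the precursor cells of brown fat, at day 0 and day 1 of differentiation toward brown adipocytes. The series holds 6 wild-type libraries, 3 per day, and its title concerns deletion of RUNX1 or RUNX2, but no deleted sample is among those used here. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Libraries were made with the TruePrep DNA Library Prep Kit V2, per the labels' protocols.

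The submitters' processing notes name the mm10 build, Trim Galore 0.6.7, Bowtie2 2.4.4, SAMtools 1.15.1, deepTools 3.5.1, MACS2 2.2.7.1, DiffBind 3.8.4 and HOMER 4.11, without saying in which step each was used. Peaks were called per library and not on pooled reads with MACS2 2.2.7.1, per the file headers. The headers record paired-end fragments, no control library, a q cutoff of 0.05, at most 1 fragment per position and a local background over 10000 bp. A shift of 100 bp and an extension of 200 bp stand on the recorded command line, but the paired-end mode builds its signal from whole fragments. A peak therefore marks fragment density and not the position of the transposase cut. The pileup column is the signal at the summit as a whole number of fragments, deposited without scaling to library size. The authors' −log10 p and −log10 q columns set that pileup against the local background of the same library. The authors' fold enrichment is the ratio of pileup to that background within a library, with 1 added to each, so it also varies with depth. These values per peak are the authors' own and served only to rank or filter peaks within a list and to describe regions. The length column gives the width of each peak in bp, per the file headers.

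Depth was read from the fragment totals in the headers and ranged from 4919755 to 11011889 fragments per library. Within each day, peak number did not strictly follow fragment number. With all else equal, a shallower library gives fewer peaks at the same cutoff, and day 1 was shallower than day 0. Comparisons of presence and absence were therefore made on the deposited lists and on equal lists, in which each library kept its 12556 strongest peaks by q, the length of the shortest list. In an equal list, absence means a lower rank and not a lack of signal. Peaks on chromosomes 1 to 19, X and Y were used. Peaks of all 6 libraries that overlapped by at least 1 bp were merged into regions. A day 0 only region had a peak in 3 of 3 day 0 libraries and 0 of 3 day 1 libraries, and a day 1 only region was the mirror. No test per region was made, since the calls are presence or absence and exact permutation of 3 libraries against 3 cannot give a two-sided p below 0.1. A model of read counts per region could go lower, but read counts were not used here.

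The gene table belongs to GRCm38, the assembly that mm10 names, and lists the start and end of 21887 protein-coding genes without strand or exons. The planned distance to transcription starts was therefore replaced by the distance to either end of a gene. Gene end means here the 1 kb on either side of the annotated start or end, so it covers promoters and the far ends of genes alike. Intron, exon and UTR positions are not given for the same reason. Of the summits in the equal list of day 0 replicate 1, 41.1% lay within 1 kb of a gene end, against 5.73% after the gene ends were moved by 50 kb. Regions were assigned to the coding gene with the nearest end, at most 100 kb away. A planned search for 21 transcription factor motifs needs the genome sequence, which was not used here, and was not run.

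Values with 1 number per library were compared by exact two-sided permutation of the 6 libraries. Overlap between libraries was the Jaccard index, the bp shared by 2 lists over the bp in either, tested one-sided over the 10 splits into 3 and 3. For 14 gene lists fixed before the data were examined, the number of genes with at least 1 day 0 only or day 1 only region of the equal lists was set against 10000 random lists matched on regions per gene. The 28 p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. This is a test across genes within these libraries, not across replicates. Named genes followed a rule fixed at the same time. It takes 14 regulators and markers, the 12 regions of each day with the highest mean fold enrichment, 1 per gene, and up to 4 genes per list and class with the most regions. Genes named outside that rule are said to be so.

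Tested on simulated data, with 500 regions planted per class and 5% of peaks dropped per library, 83.8% of day 1 only and 88% of day 0 only regions were recovered against 85.7% expected, with 1 false region. Peaks were dropped independently and at the same rate in every list. The simulation thus does not cover false regions from differences in depth or library quality between the days. On the 11318 genes with a region, 1.25% of null lists passed 0.05, and 98% of lists with 8 of 20 planted genes did. In the random-list test of gene ends, on 8926 genes, 4% of null lists passed when matched on the number of libraries with a call. Without matching, 99% of lists with 8 of 16 planted genes passed. Null lists without matching and planted lists with matching were not simulated.

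Alternatives covered a −log10 q of at least 5, all contigs, leaving out each library, an overlap of 50%, 500 bp bins, presence in at least 2 of 3 libraries, ranking by fold enrichment, shorter lists, a window of 2.5 kb, assignment by gene body with 10 kb around it, and the replicate number as a block. Leaving out day 1 replicate 3, whose list was the shortest, lengthens the equal lists to 20069 peaks, while leaving out any other library keeps them at 12556. Added after the data had been seen were the lists without day 1 replicate 3 kept at 12556 peaks, absence of any peak on the other day, thresholds on summit height per 1000000 fragments, and random-list tests of gene ends. The rule for when a list's count differed between settings was also set after those counts were known. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.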

Results

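ATAC-seq peak lists were analysed from brown pre-adipocytes at day 0 and day 1 of differentiation toward brown adipocytes, with 3 libraries per day. Day 0 libraries held 11011889, 8127635 and 9160156 fragments and day 1 libraries 4919755, 5603667 and 7302457. Coordinates are those of mm10.

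The first comparison asks how much of the open chromatin differed between the days. Day 0 cells had 45572 ± 8719 peaks (SD, n = 3) and day 1 cells 18633 ± 5501 (SD, n = 3), a ratio of 2.45, and the ranges of the days did not overlap. The exact permutation p was 0.1, the smallest this test can give for 3 libraries against 3. Peaks covered 15.8 ± 4.14 Mb at day 0 and 6.21 ± 2.27 Mb at day 1 (SD, n = 3 each, exact permutation p = 0.1). Median peak width was 283 ± 28.9 bp and 276 ± 21.7 bp, a difference within the spread of the replicates (n = 3 each, exact permutation p = 0.9).

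Fragment number moved with the day. Per 1000000 fragments, the day 0 lists held 5041, 5167 and 4281 peaks and the day 1 lists 4079, 4153 and 1719. Day 1 replicate 3 stood apart, with more fragments than the other day 1 libraries and 12556 peaks against their 20069 and 23274. Its median summit height in the 9136 regions shared by all libraries was 1.78 fragments per 1000000, against 2.62 to 3.94 in the other libraries.

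**Figure D1:**
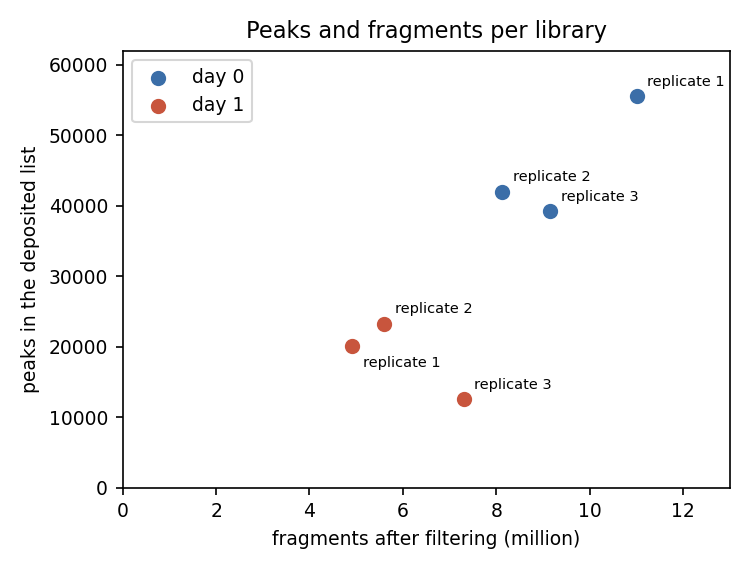
Each point is 1 library, with fragments after filtering, in units of 1000000, on the x axis and peaks in the deposited list on the y axis, blue for day 0 and red for day 1. The day 0 lists hold 39211 to 55511 peaks and the day 1 lists 12556 to 23274, with day 1 replicate 3 lowest at 7302457 fragments.

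Libraries of the same day shared more peak sequence than libraries of different days. The mean Jaccard index was 0.513 between day 0 libraries, 0.416 between day 1 libraries and 0.272 across days. In equal lists of 12556 peaks the values were 0.561, 0.486 and 0.353. The difference within minus between days was 0.193 in deposited and 0.170 in equal lists, against at most 0.0139 and 0.0020 in the other splits of the libraries. The one-sided exact permutation p was 0.1 for both, the smallest possible over 10 splits.

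The second comparison asks which regions were open on 1 day and not the other. In the deposited lists, 12066 regions were day 0 only and 418 day 1 only, among 68913, and 9136 were shared by all 6 libraries. In equal lists the classes were closer in size, with 2135 day 0 only and 1339 day 1 only regions among 23438, and 5339 shared by all. Leaving out day 1 replicate 3, the shortest list, gave 2318 and 1956 with lists kept at 12556 peaks, and 3805 and 3002 with lists lengthened to 20069, the shortest of those left.

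Regions of either day lay away from gene ends more often than shared regions did. In equal lists, 68.0% of shared regions, 3.00% of day 0 only regions and 27.2% of day 1 only regions lay within 1 kb of a gene end. In deposited lists the shares were 60.7%, 6.30% and 5.26%. Of the 2135 day 0 only regions, 1423 had no day 1 peak of any strength. Of the 1339 day 1 only regions, 253 had no day 0 peak of any strength, of which 12 lay at gene ends. The other 1086 had a day 0 peak that ranked below the 12556 strongest of its library. Such a peak need not be lower than the day 1 peak, since the day 0 libraries were deeper.

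The 12 strongest day 0 only regions by mean fold enrichment had values from 19.4 to 21.8. The first lay inside Myo5c, which encodes a myosin motor, on chromosome 9 from 75236667 to 75237202, with a fold enrichment of 21.8 ± 0.892 (SD, n = 3). Others lay nearest to Reep3, Olfm3, Dars, Mettl7b, Gja1, Rspo2, Zfat, Etv5, Sbk3, Herc3 and Tln2. Of the 12, 6 had a weaker day 1 peak, those of Reep3, Dars, Mettl7b, Gja1, Etv5 and Herc3. Gja1 encodes the gap junction protein connexin 43, and its region lay 96.3 kb from the gene. Rspo2 encodes a secreted enhancer of Wnt signalling, and its region inside the gene, on chromosome 15 from 43158201 to 43158578, had no day 1 peak.

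The 12 strongest day 1 only regions had mean fold enrichments from 13.1 to 15.8. Depth differed between the days, so these values cannot be set against those of day 0. The first lay 16.4 kb from Smc5, on chromosome 19 from 23189824 to 23190193, with a fold enrichment of 15.8 ± 1.05 (SD, n = 3), and was the only one of the 12 with no day 0 peak. The rest lay nearest to Ptdss1, Prkd1, Btg1, Amotl2, Atp2b1, Tmem100, Hal, Gm19774, Prkaa1, Mbnl2 and Ice2. Prkaa1 encodes a catalytic subunit of the energy sensor AMPK, and its region inside the gene, on chromosome 15 from 5149181 to 5149754, had a fold enrichment of 13.4 ± 1.52 (SD, n = 3). In the deposited lists 8 of these 12 genes, Amotl2, Atp2b1, Btg1, Gm19774, Ice2, Mbnl2, Prkaa1 and Prkd1, had more day 0 only than day 1 only regions.

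The third comparison asks whether groups of genes tied to adipocyte differentiation lay near regions of 1 day. Of 28 tests, 1 passed the threshold. Day 0 only regions lay near 4 of the 6 endothelial marker genes with any region, Cdh5, Kdr, Pecam1 and Vwf, against 0.543 expected from random lists (permutation p = 0.001, adjusted p = 0.028). Gene ends of this list carried few peaks, at Kdr in 3 and Tal1 in 2 of 3 deposited day 0 lists and at none of the other 10 markers. The call was lost under 8 of 10 alternatives, with adjusted p from 0.0056 to 1 over the 10. The count stayed at 4 of 6 against 0.703, 0.714 and 0.653 expected without day 0 replicate 1, day 0 replicate 3 and day 1 replicate 2 (adjusted permutation p = 0.0504, 0.101 and 0.056). It was 4 of 6 against 0.676 without day 1 replicate 3 at 12556 peaks per list (adjusted permutation p = 0.0691), and 3 of 8 against 1.42 at 20069 (0.849).

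The list of mature adipocyte lipid genes covers lipid storage, uptake and release and also holds others, such as the hormone genes Retn and Adipoq. It had day 1 only regions near 5 of 19 genes, Acsl1, Fabp4, Lipe, Retn and Scd1, against 2.10 expected (adjusted permutation p = 0.559). Leaving out day 1 replicate 3 gave 8 of 19 against 2.92 at 12556 peaks per list (adjusted permutation p = 0.0691). At 20069 peaks it gave 13 of 21 against 4.17 (adjusted permutation p = 0.0056), and the 13 were Acsl1, Adipoq, Agpat2, Aqp7, Cd36, Cidec, Fabp4, Lipe, Plin2, Plin4, Pnpla2, Retn and Scd1. Of these, Scd1, Agpat2, Aqp7, Cd36, Cidec, Plin2, Plin4 and Pnpla2 fall outside the rule for named genes and were chosen after their values were seen, as were Tal1 and Runx1t1. Without day 1 replicate 1 it was 9 of 19 against 2.87 (adjusted permutation p = 0.0168), and the list passed under 2 of 10 alternatives, with adjusted p up to 1. Acsl1, which activates long-chain fatty acids, had 2 day 1 only regions with no day 0 peak, on chromosome 8 from 46426345 to 46426599 and from 46404244 to 46405010, and a day 0 only region from 46429583 to 46430355. In that order, these regions lay 44.6, 66.4 and 41.1 kb from the gene.

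Glucocorticoid- and cAMP-responsive genes had day 1 only regions near 7 of 19 genes against 2.97 expected (permutation p = 0.0292, adjusted p = 0.273, and 0.126 to 1 over 10 alternatives). The count without day 1 replicate 3 was 7 of 19 against 4.40 at 12556 peaks per list (permutation p = 0.223) and 6 of 19 against 6.02 at 20069 (permutation p = 1). The 7 included Pde4d and Pde4b, which degrade cAMP, and Pdk4, which limits glucose oxidation, and Pde4b also had a day 0 only region. Extracellular matrix and fibroblast genes had day 0 only regions near 10 of 23 genes against 7.12 expected (adjusted permutation p = 0.70). Among these regions, 3 lay nearest to Thy1, 3.49, 58.8 and 97.8 kb away, and 2 each nearest to the collagen genes Col6a1 and Col6a3. The count without day 1 replicate 3 was 11 of 23 against 7.77 at 12556 peaks per list (adjusted permutation p = 0.568) and 17 of 23 against 10.6 at 20069 (0.0532), and the list passed under 0 of 10 alternatives, with adjusted p up to 1.

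The RUNX family had day 0 only regions near 3 of 4 genes, Runx1, Runx2 and Cbfb, against 1.10 expected (adjusted permutation p = 0.472). Without day 0 replicate 2 the count was 4 of 4 against 1.18 (adjusted permutation p = 0.0336), and without day 1 replicate 3 it was 3 of 4 against 1.06 at 12556 peaks per list and 2 of 4 against 2.06 at 20069, with adjusted p up to 1 over 10 alternatives. In deposited lists it was 2 of 4, Runx1 and Runx1t1, against 3.19 expected (adjusted permutation p = 0.856). Housekeeping controls had day 1 only regions near 5 of 14 genes against 1.40 (adjusted permutation p = 0.188), and 6 of 14 against 1.71 without day 0 replicate 2 (adjusted permutation p = 0.0485, and up to 1 over 10 alternatives). Without day 1 replicate 3 it was 6 of 13 at 12556 peaks per list (adjusted permutation p = 0.0691) and 1 of 14 at 20069.

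The other lists did not pass in either class. Day 1 only regions lay near 3 of 15 thermogenic and brown fat genes, 3 of 20 adipogenic transcription factors, 5 of 24 precursor and anti-adipogenic genes, 1 of 18 cell cycle genes, 1 of 4 myogenic genes and 0 of 13 AP-1 and immediate early genes. In that order, random lists gave 1.45, 3.96, 4.23, 1.48, 0.41 and 2.19. Day 0 only regions lay near 0 of 15, 5 of 20, 3 of 24, 0 of 18, 0 of 4 and 3 of 13 genes of these lists. Bone and cartilage genes and immune cell markers had neither class near their 9 and 4 genes with a region in these equal lists. Without day 1 replicate 3 at 20069 peaks per list, each class lay near 2 of 10 bone and cartilage genes and 1 of 5 immune cell markers. In deposited lists, day 0 only regions lay near 5 of 16 bone and cartilage genes against 6.46 expected. For AP-1 and immediate early genes it was 12 of 13 against 8.03 (adjusted permutation p = 0.274). Their day 1 only count without day 1 replicate 3 at 20069 peaks was 0 of 13 against 4.12 (adjusted permutation p = 0.0747). Ranking by fold enrichment went the other way, with 1 of 12 against 2.43 for day 0 only and 4 of 12 against 1.81 for day 1 only regions.

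**Figure D2:**
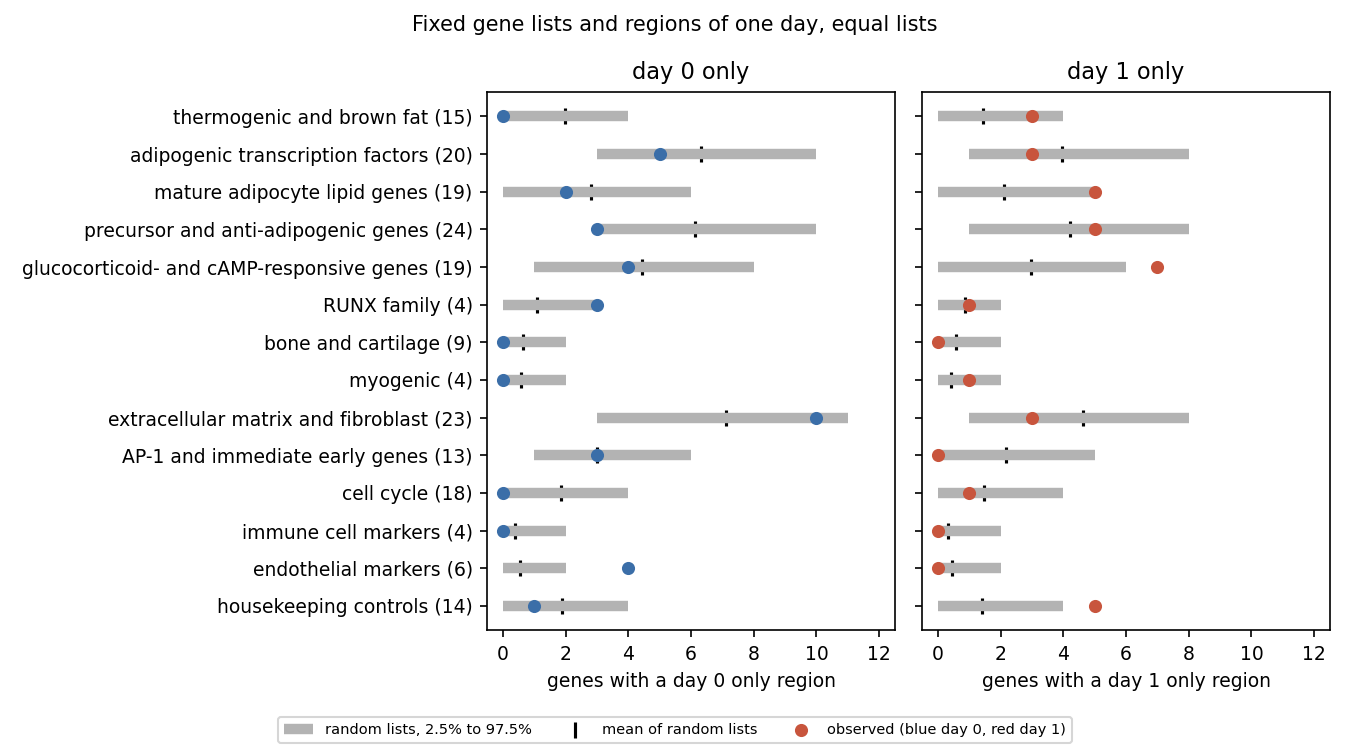
For each fixed list, with its number of genes that had a region in parentheses, the x axis gives the genes with a day 0 only (left) or day 1 only (right) region of the equal lists; points are observed counts, ticks the mean and grey bars the central 95% of 10000 random lists. Endothelial markers at day 0, with 4 genes, lie beyond the random range and pass the threshold, whereas glucocorticoid- and cAMP-responsive genes (7) and housekeeping controls (5) at day 1 lie beyond it without passing after adjustment.

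Among the regulators and markers named in advance, Pparg, which encodes the main transcription factor of fat cell formation, had regions of both days in equal lists. Inside the gene on chromosome 6, day 0 only regions lay from 115462783 to 115463444 and from 115480046 to 115480784, with fold enrichments of 12.7 ± 2.03 and 11.97 ± 0.376 (SD, n = 3 each), and neither had a day 1 peak. Beyond the gene, 21.2 kb from its end, a day 1 only region from 115511459 to 115511827 had a fold enrichment of 12.6 ± 1.87 (SD, n = 3). A weaker peak overlapped it in day 0 replicate 1, with a fold enrichment of 3.98. In deposited lists Pparg had 5 day 0 only and 0 day 1 only regions. Its gene end was called in 1 day 0 and 0 day 1 deposited lists.

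**Figure D3:**
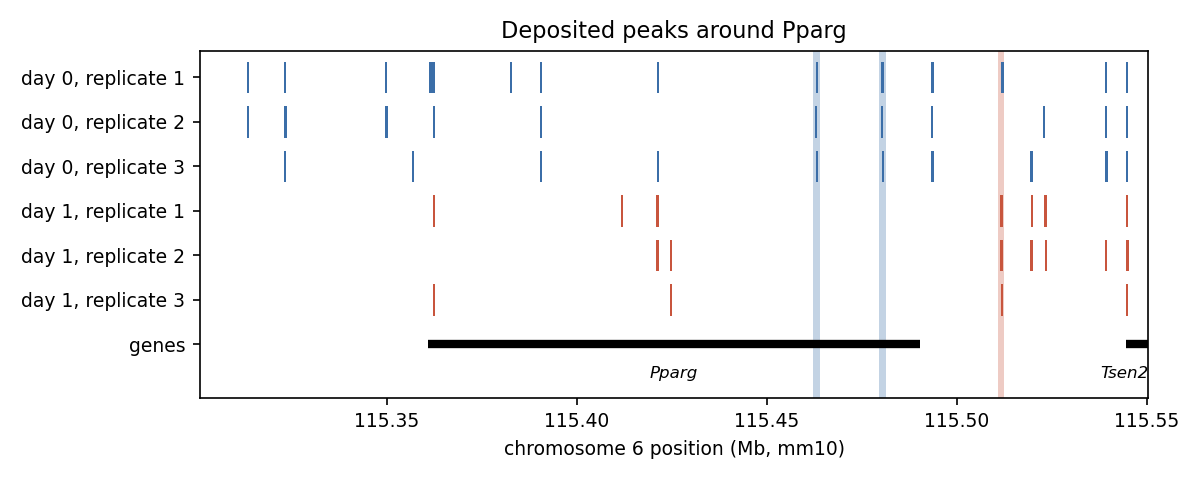
Deposited peaks of each library around Pparg on chromosome 6 (x axis, Mb), blue for day 0 and red for day 1, with gene spans as black bars. Blue shading marks the day 0 only regions inside the gene and red shading the day 1 only region from 115511459 to 115511827.

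Runx1, which encodes a RUNX transcription factor, had day 0 only regions inside the gene on chromosome 16, from 92620613 to 92621557 and from 92653894 to 92654998, and a day 1 only region from 92783697 to 92784114. Each also had a peak on the other day that ranked below the 12556 strongest of its library. At the day 1 only region, fold enrichments were 9.38, 6.02 and 4.53 in the deeper day 0 libraries and 9.34, 7.42 and 7.20 at day 1. Runx2 and Cbfb, the gene of the shared binding partner of RUNX proteins, each had 1 day 0 only region inside the gene, with fold enrichments of 12.7 ± 1.86 and 17.1 ± 0.980 (SD, n = 3 each), and both regions also had a weaker day 1 peak. The Runx2 gene end was called in 3 day 0 and 1 day 1 deposited lists and that of Cbfb in 3 and 3. Without day 1 replicate 3 and with 20069 peaks per list, Cbfb had more day 1 only than day 0 only regions. Runx3 had no region in any list.

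Ucp1, the gene of the uncoupling protein of brown fat, had no region in any list. Ppargc1a, a coactivator gene of mitochondrial biogenesis, had a gene-end peak in 3 day 0 and 0 day 1 deposited lists. The corresponding counts were 3 and 1 for Ebf2, 3 and 2 for Cebpd, 3 and 3 for Cebpa, 2 and 2 for Cebpb, and 1 and 1 for Adipoq. Prdm16 had none. Fabp4, which encodes the fatty acid binding protein of adipocytes, had a day 1 only region 5.32 kb from the gene on chromosome 3, from 10213785 to 10214077, with a fold enrichment of 8.21 ± 1.09 (SD, n = 3). The day 0 libraries also had peaks in that region of Fabp4, with fold enrichments of 7.70, 7.21 and 4.47. Its gene end was called in 3 day 0 and 2 day 1 deposited lists.

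The fourth comparison asks how far peaks concentrated at gene ends. In equal lists, 40.5 ± 0.978% of day 0 peaks and 50.5 ± 1.25% of day 1 peaks lay within 1 kb of a gene end (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). All day 1 libraries lay above all day 0 libraries. The difference was 10.1 percentage points, and without day 1 replicate 3 it was 10.1 at 12556 peaks per list and 6.48 at 20069. It was 18.9 in deposited lists (23.9 ± 2.52% and 42.8 ± 6.88%, SD, n = 3 each). Coding genes with a gene-end peak numbered 5981 ± 174 at day 0 and 7254 ± 258 at day 1 in equal lists, and 10572 ± 672 and 8396 ± 1174 in deposited lists (SD, n = 3 each, exact permutation p = 0.1 for both).

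**Figure D4:**
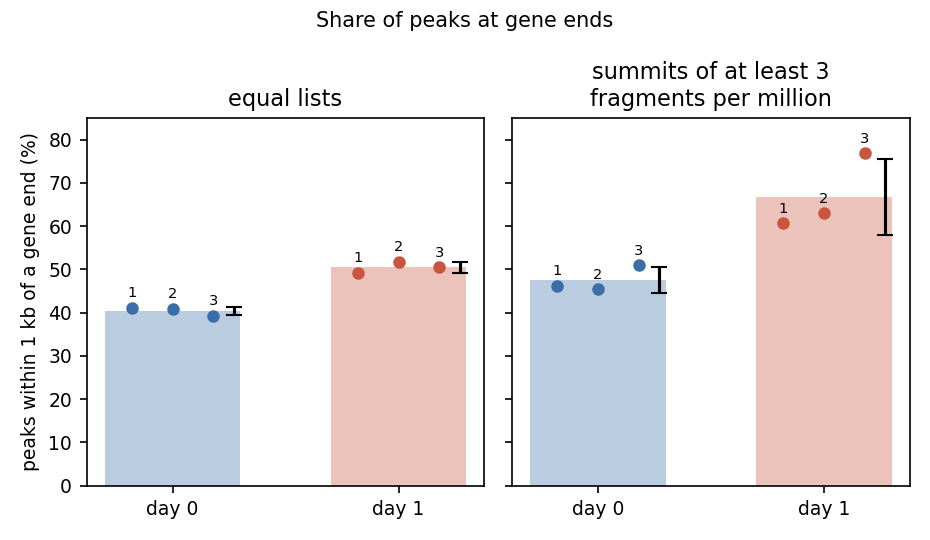
Share of peaks within 1 kb of a gene end (y axis, percent) in equal lists (left) and among deposited peaks with summits of at least 3 fragments per 1000000 of the library (right); bars are means, error bars SD, and points libraries numbered by replicate. Day 1 libraries lie above day 0 libraries in both panels, at 49.3 to 51.8% against 39.3 to 41.1% on the left.

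Mature adipocyte lipid genes had a gene-end peak at 6, 6 and 5 of 25 genes in the day 0 libraries and 12, 14 and 14 in the day 1 libraries of the equal lists (means 5.67 and 13.3, n = 3 each, exact permutation p = 0.1, adjusted p = 0.28). In deposited lists the counts were 16, 16 and 15 at day 0 and 15, 17 and 14 at day 1 (n = 3 each, exact permutation p = 1). Extracellular matrix genes had 11 ± 1 and 10 ± 1 of 24 genes in equal lists and, in deposited lists, 23, 21 and 21 at day 0 and 18, 15 and 9 at day 1 (n = 3 each, exact permutation p = 0.5 and 0.1). No list passed the adjusted threshold, which exact permutation of 3 libraries against 3 cannot reach, and 10 of the 14 lists changed direction between equal and deposited lists.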

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

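Tests without day 1 replicate 3 at kept list length, on summit height, on absence of any peak and against random lists of gene ends were chosen after the data had been seen. Peak number, covered genome, Jaccard difference and gene-end share in planned settings kept their direction; exact permutation of so few libraries could not pass 0.05. The motif analyses and their alternatives were not run. The labels do not say whether libraries with the same replicate number are paired. Deviations of day 0 and day 1 libraries correlated between −0.0098 and 0.0103, which shows no pairing but cannot exclude one. With the replicate block, the exact sign-flip p was 0.25 for the differences in peaks, covered Mb and gene-end share (−26939, −9.55 and 10.1). It was 0.75 for width (−7.33 bp), and no call changed. Depth limits what absence at day 1 shows, and the causes of the changes below were not tested.

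Day 0 only and day 1 only regions of equal lists were 1380 and 825 at −log10 q of at least 5, 965 and 556 with the equal lists shortened to N divided by 2, 3570 and 2952 with at least 2 of 3 libraries, and 1423 and 253 with no peak of any strength on the other day. Day 1 only equal regions were 835 at 50% overlap and 381 in 500 bp bins. Day 0 only and day 1 only regions of deposited lists were 4968 and 119 in bins, 21207 and 1386 with at least 2 of 3 libraries, and 1186 and 43 with summits of at least 3 fragments per 1000000 of the library. Leaving out 1 library gave 2350 to 3805 and 1517 to 3002 in equal lists and 446 to 1178 day 1 only regions in deposited lists. The highest were without day 1 replicate 3, where equal lists lengthen to 20069 peaks; kept at 12556, they gave 2318 and 1956 and a gene-end share difference of 10.1 points, with 0 gene list calls. The width difference was 10.7 bp at −log10 q of at least 5 and from −24.0 to 2 bp without 1 library. The gene-end share difference was −8.65 points with summits of at least 10 per 1000000.

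Gene list calls were 0 when ranked by fold enrichment, by gene body or in deposited lists, and 0 to 3 without 1 library. Endothelial genes with day 0 only regions were 2 of 6 against 0.438 expected, 2 of 4 against 0.173 and 4 of 10 against 4.31 in these settings (adjusted permutation p = 0.679, 0.655 and 1). They numbered 3 to 5 without 1 library. Random lists gave 1 gene-end call in equal and 4 in deposited lists, and 0 and 2 when matched, against 0 by libraries. In deposited lists the day 1 minus day 0 gene-end difference turned to −3.67 for thermogenic and for bone genes, −3.33 for precursor and for AP-1 genes, −2.67 for adipogenic factors, −1.67 for cell cycle and for housekeeping genes, −0.667 for RUNX and for myogenic genes and −0.333 for lipid genes; AP-1 genes gave −1.33 with a 2.5 kb window. Day 1 only minus day 0 only regions turned in deposited lists to −1 for Actb, Amotl2, Atp2b1, Lipe, Nr3c1, Pde4d, Prkaa1, Prkd1 and Tcf7l1, −2 for Klf15 and Pdk4, −3 for Ccn1 and Ebf2, −4 for Gm19774 and Wwtr1 and −5 for Btg1. It was −1 for Wwtr1 by fold enrichment. Without 1 library it reached 1 for Adipoq, Cbfb and Pdgfrb and −1 for Ccn1 and Wwtr1, each without day 1 replicate 3 at 20069 peaks per list, and none of these turned at 12556.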

Other observations

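Apart from the count of gene list calls over other splits, the tests in this part were chosen after the results they bear on had been seen. Genes whose gene end was called in 3 of 3 day 1 and 0 of 3 day 0 deposited lists numbered 10, against 531 in the opposite direction and at most 140 for any other 3 libraries against the rest. Groups of 3 libraries mixed over the days gave 140, 52, 50, 39, 24 and 11, and the other mixed groups 0 to 7. The day 1 count therefore does not stand out from mixed groups. The 10 genes called only at day 1, named after their values were seen, were Ankrd23, Bcl2l10, Cidec, Hacd4, Letmd1, Mrap, Mrpl18, Nfe2, Osbpl11 and Zbtb16. Cidec codes for a protein of lipid droplets, and its peaks, on chromosome 6 within 113434796 to 113436033, had a fold enrichment of 6.10 ± 0.557 (SD, n = 3). Mrap codes for an accessory protein of melanocortin receptors, and Zbtb16 is a glucocorticoid-responsive gene of the fixed lists. The Mrpl18 peaks lay nearest to an end of the neighbouring gene Tcp1.

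The lipid gene ends raise a hypothesis, that mature adipocyte lipid genes may gain gene-end peaks beyond coding genes in general. Against 10000 random lists, their change was 7.67 genes with 2.29 expected in equal lists (adjusted permutation p = 0.0048) and −0.333 with −3.69 expected in deposited lists (adjusted permutation p = 0.0322). Matched on the number of libraries with a call, adjusted p was 0.0672 in equal and 0.014 in deposited lists. The largest value, 0.0672, misses the threshold, so the hypothesis stays open. In deposited lists, glucocorticoid- and cAMP-responsive genes also lay above random lists (adjusted permutation p = 0.0070, and 0.042 matched), and immune cell markers (0.0070) and bone and cartilage genes (0.0271) lay below unmatched ones only.

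For the lower number of day 1 peaks, fewer fragments are argued against for day 1 replicate 3, which had 0.539 times the peaks of replicate 2 with more fragments. Its summits in the 9136 shared regions were lower per 1000000 fragments than in each day 0 library, with median log2 ratios of at most −0.46, so lower signal over background may account for its short list. For replicates 1 and 2 lower signal is argued against only within those shared regions, with median log2 ratios no lower than −0.0929. Across the days, summit height there did not follow peak number. Day 0 replicate 3 had a median of 2.62 per 1000000 and 39211 peaks, against 3.93 and 23274 in day 1 replicate 2, but depth differed too. Within each day, the library with the lowest median also had the fewest peaks. Regions not called in all libraries were left out, so lower signal there stays possible for day 1 replicates 1 and 2. Fewer fragments cannot be told apart from a biological difference between the days for these libraries, which held up to 7896 peaks of at least 3 fragments per 1000000 of the library, between the day 0 values of 5101 and 10533. At 1.5, the lowest of 7 heights, their 15500 and 16431 peaks lay below every day 0 library (lowest 18661), by less than the day 0 SD, and at the other 6 they did not both do so; away from gene ends they did so at 1.5 and 2.

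The higher share of gene ends at day 1 persisted with summits of at least 3 fragments per 1000000 of the library, where the lowest day 1 share exceeded the highest day 0 share by 9.60 percentage points, which argues against fewer fragments alone. Of 7 heights looked at, 5 separated the days; at 8 and 10, day 1 replicate 3 kept 30 and 15 peaks and lay below, while replicates 1 and 2 lay above every day 0 library at all 7. As far as summits in the shared regions measure signal, lower signal is argued against by day 1 replicates 1 and 2. These exceeded day 0 replicates 1 and 2 by at least 14.4 points at the height of 3. Rank within the list may account for day 1 only regions at gene ends, of which 96.7% overlapped a deposited day 0 peak, against 75.3% away from gene ends. The deposited day 0 lists are longer than the equal lists and held a gene-end peak for 53.1% of coding genes. The overlap therefore cannot tell rank from a gain in signal. A difference between the days themselves stays a hypothesis.

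The day 0 only regions near endothelial markers could come from endothelial cells in the day 0 cultures. Of the 12 markers, 2 had a gene-end peak in any deposited day 0 list, or 16.7%, against 53.1% of all coding genes. Immune cell markers, another cell type, had gene-end peaks at 6, 5 and 5 of 12 genes in the deposited day 0 lists and 2, 1 and 0 at day 1. Of all 21887 coding genes, 11291, 10465 and 9961 had one at day 0 and 8685, 9398 and 7105 at day 1. The marker counts at day 0 thus lay near the general share. Cd14, Cd68, Cx3cr1 and Spi1 were called in 3 of 3 day 0 lists. Ptprc, Adgre1, Itgam, Csf1r, Cd3e and Tyrobp were called on neither day. These genes were named after their values were seen. Deposited day 0 only regions lay near 5 of 9 immune cell markers with a region against 2.76 expected (adjusted permutation p = 0.654). Since a small share of such cells need not give gene-end peaks, endothelial cells cannot be told apart from chance or from regulation of neighbouring genes, and the Cdh5 region lay 78.5 kb from that gene.

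The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split alone, 1 of the 10, gave 12484 regions in both classes in deposited lists, with at most 549 in others, and 3474 in equal lists, with at most 131. It gave 1 gene list call, and the other splits 0. With at most 131 regions in both classes, the other splits could hardly give a call, so no conclusion is drawn from this count.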
